A study of Mus musculus with 43 samples.

How the data were processed

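Liver RNA of 36 male mice was sequenced, giving 43 libraries in 10 groups and 2 tables. The deposited values are log2 CPM (read counts scaled for library size, on a log2 scale), which the labels call moderated. Per the submitters' processing notes, reads were processed with STAR (2.0.4b), Subread and featureCounts (1.4.5) and the mouse build GRCm38. The order, settings, strand rule and gene annotation of these steps are not given in the sources used here, so antisense and overlapping genes could not be told apart by strand.

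The values were tested for the reads behind them. In every library each value equalled the log2 of a whole read number plus 0.5, divided by an effective library size, on the CPM scale, for 100% of values within a tolerance of 0.01 reads. The recovered reads summed to 13.8 M to 23.9 M per library in the hemizygous table and to 38.2 M to 90.1 M in the homozygous table. The effective library size was 0.875 to 1.14 times that sum in the hemizygous table and 0.900 to 1.18 times in the homozygous table, so the deposited values carry a scaling between libraries. A gene with 3 reads stood at a median of -2.47 log2 CPM in the hemizygous table and -4.21 in the homozygous table, and values near these levels are imprecise. Among values under 40 reads, 47.2 to 51.1% were even numbers in the hemizygous and 46.4 to 64.1% in the homozygous libraries. Whether read ends of pairs were counted separately in some of these is not known.

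There were 14737 lines for 14622 genes in the hemizygous table and 13796 lines for 13741 genes in the homozygous one. Of these lines 115 and 55 repeated a gene with identical values and were dropped. In 21 and 20 lines the symbol had been turned into a date, and symbols were restored from the gene identifiers. GENCODE M21, on GRCm38, named 14594 and 13736 of the identifiers and gave the coordinates printed here. The hemizygous table held 1 further column of per-sample values that matched no sample label and was not used. The 7 WT and LIRKO mice occur in both tables, and each of the 7 was nearest to its own library in the other table, with correlations across genes of 0.960 to 0.964. The tables were scaled separately, so tests were made only within a table, and these mice were never counted as separate animals.

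Groups came from the sample labels. The comparisons, tests, samples in each fit, gene lists, rule for named genes and most alternative settings were fixed before the data were examined. Genes with at least 0 log2 CPM in at least 3 libraries were tested, 13596 in the hemizygous table and 13690 in the homozygous table. limma (3.58.1, in R 4.3.3) was fitted to the deposited values with 1 mean per group over all groups of a table, with moderated variances that followed a trend in expression. Its two-sided p-values were adjusted by Benjamini and Hochberg over all genes of a comparison, with a threshold of 0.05. Every adjusted p of a gene printed here comes from this test. Fold changes are differences of log2 values with 0.5 reads added, which understates the change of low genes.

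For 32 gene lists with 630 different genes, of which 602 and 593 were found in the 2 tables, camera of limma was run with its preset correlation, adjusted over the lists of a comparison. None of its calls held with a correlation estimated from the data, and that adjusted p is printed beside each, after the word estimated. Counts over a list alone adjust p over its members only. Not all of its 134 calls are described. The lists were written from general knowledge of liver biology, and some genes stand in more than 1 list.

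Genes were named by a rule. In each comparison the 5 genes with the largest increase and the 5 with the largest decrease were taken among genes with a symbol, an adjusted p under 0.05, a mean of at least 2 log2 CPM over the compared groups and no overlap between the groups' values, passing over predicted genes and pseudogenes. For the interactions and for Zstar against Z up to 3 in each direction were taken, without the overlap condition for the interactions, and none for LIRKO against WT in the homozygous table. Insr, Foxo1 and the mouse Serpina1 genes were followed in all comparisons, and each list gave up to 4 members with the smallest p, or 6 where at least 50% of the members passed. Some genes that the rule took are not reported here and were not replaced. Genes shown for the homozygous table of LIRKO against WT and the genes drawn in the plots were chosen after their values were seen.

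The test was checked on simulated data with known changes. For Z against WT (13465 genes) it recovered 38.0% of genes changed 1.5-fold, 68.8% of those changed 2-fold, 91.8% at 4-fold and 95.9% at 8-fold. For ZZ against WT (13515 genes) these shares were 25.5, 74.0, 83.7 and 98.0%, and for the F1KO difference (13487 genes) 14.6, 73.9, 78.0 and 95.9%. Wrong calls made up 2.48 to 4.83% of calls over the 6 comparisons simulated.

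The alternatives fixed in this way covered the filter, the added constant, median and quantile scaling, library weights, the variance prior, the samples in the fit, a minimum change, other control groups, other gene set tests and each mouse left out. Alternatives chosen after seeing the data were voom weights on the recovered reads, fits without libraries above 0 log2 CPM of the pancreatic gene Prss2, fits without ZZ LIRKO mice 1876 and 1877, and a clock value as a covariate. Count-based tests on the recovered reads, planned at first, were not run, because the deposited unit is a log value. Other splits of the samples were drawn with seed 20240611. Plots were made with matplotlib (3.10.9) in Python 3.11.15.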

Results

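Liver RNA was sequenced from male mice aged 4 to 5 months on a mixed C57BL6/J and FVBN background. PiZ mice carry a human transgene for the Z form of alpha-1-antitrypsin, whose Z form folds poorly and is retained in the endoplasmic reticulum. LIRKO mice lack the insulin receptor in the liver, and F1KO marks the additional knockout of FOXO1, a transcription factor that insulin signalling keeps out of the nucleus. The 43 libraries from 36 mice formed 10 groups in 2 tables. The hemizygous table held 3 wild-type (WT) mice, 4 LIRKO mice, 5 mice with a hemizygous transgene (Z), 4 Z LIRKO mice, 5 further PiZ mice whose label carries an asterisk (written Zstar here) and 5 Z LIRKO F1KO mice. The homozygous table held 3 WT, 4 LIRKO, 3 ZZ and 7 ZZ LIRKO mice. Its 7 WT and LIRKO mice were the same animals as in the hemizygous table.

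The targeted genes were compared with the labels before any other gene. Insr, the insulin receptor gene (chromosome 8, 3122061 to 3279617, GRCm38), stood at 7.12 ± 0.10 (SD, n = 3) log2 CPM in WT and 5.96 ± 0.16 (SD, n = 4) in LIRKO livers of the hemizygous table. It fell by 1.16 ± 0.12 log2 units (SE, limma, adjusted p = 1.57e-07). It was also lower in Z LIRKO than in Z (-1.25 ± 0.10, adjusted p = 2.74e-09), in Z LIRKO F1KO than in Zstar (-1.60 ± 0.10, adjusted p = 4.26e-11) and in ZZ LIRKO than in ZZ (-0.79 ± 0.11, adjusted p = 8.46e-05). Every library of a LIRKO group lay below every library without LIRKO in its table. Foxo1 (chromosome 3, 52268336 to 52353221) stood at 5.53 ± 0.21 (SD, n = 5) log2 CPM in Zstar and 2.76 ± 0.14 (SD, n = 5) in Z LIRKO F1KO livers (a change of -2.77 ± 0.13, adjusted p = 2.14e-13). Among the other groups Foxo1 was higher in Z than in WT (0.92 ± 0.15, adjusted p = 2.77e-04). It was lower in Z LIRKO than in Z (-0.45 ± 0.14, adjusted p = 0.0125) and in Zstar than in Z (-0.49 ± 0.13, adjusted p = 0.0168). Its changes in LIRKO against WT (0.05 ± 0.15, adjusted p = 0.843) and ZZ against WT (-0.50 ± 0.29, adjusted p = 0.212) did not pass. In fits of the compared groups alone Foxo1 passed in ZZ against WT (-0.50), but not in Z LIRKO against Z (-0.45) or Zstar against Z (-0.49). It did not pass for Z LIRKO against Z and Zstar together (-0.21) or for Zstar against Z without Z mouse 1443 (-0.39). Insr was lower in ZZ than in WT (-0.52 ± 0.13, adjusted p = 0.00648) without LIRKO, but did not pass without libraries above 0 log2 CPM of Prss2 (the Prss2 libraries, -0.55). The human transgene averaged between 11.89 and 12.34 log2 CPM in the 4 PiZ groups of the hemizygous table, against 4.32 ± 0.12 (SD, n = 3) in WT and 4.17 ± 0.34 (SD, n = 4) in LIRKO. The transgene was not analysed here in the homozygous table.

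**Figure D1:**
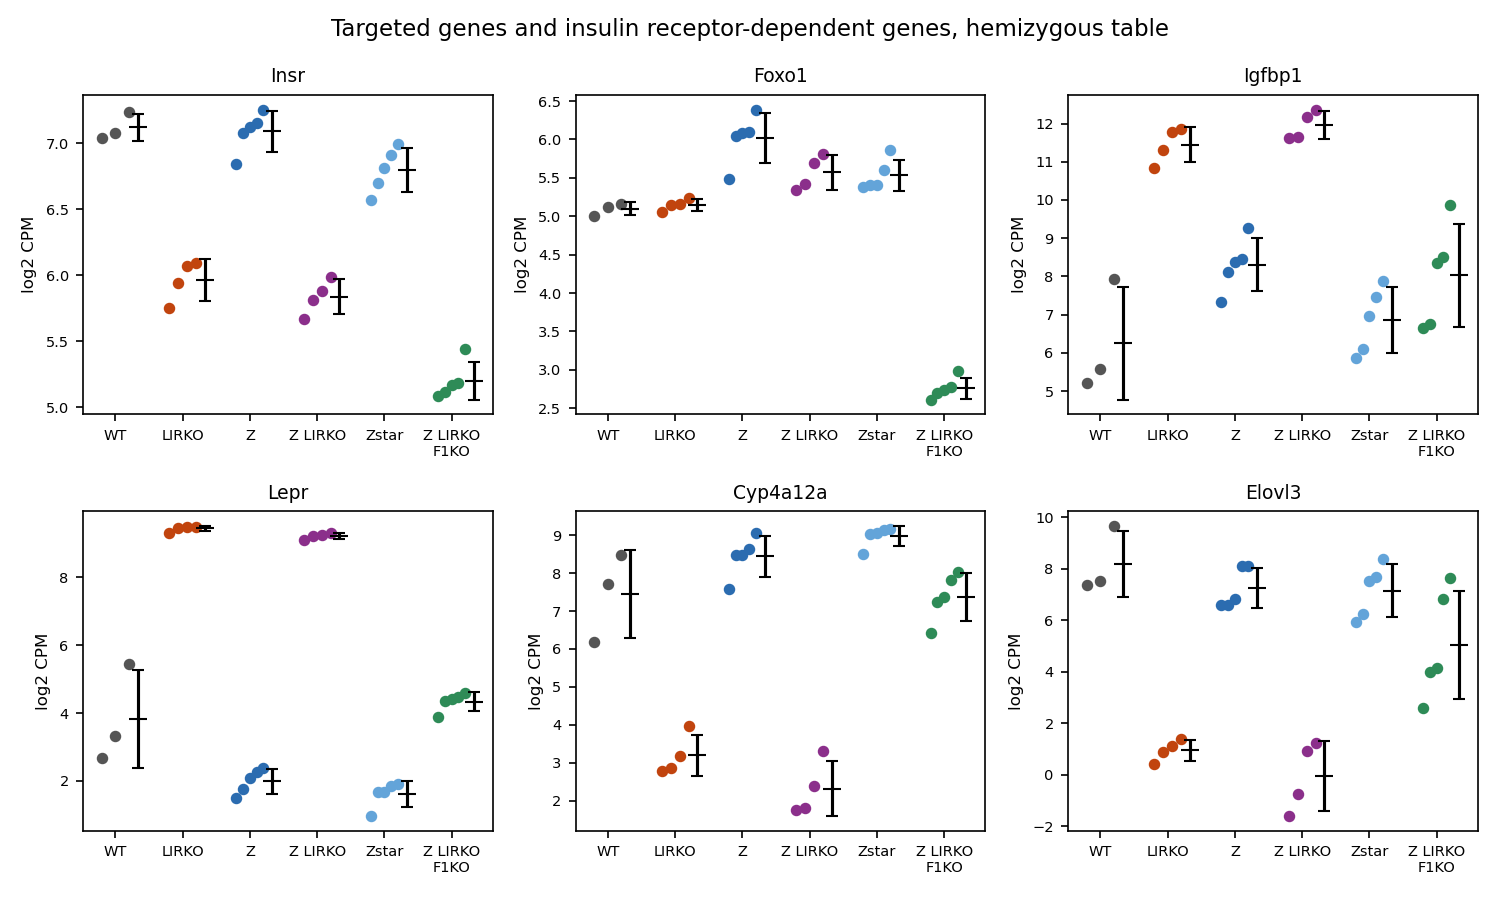
Level of 6 genes (log2 CPM, vertical axes) in the 6 groups of the hemizygous table, with 1 point per mouse and, beside the points, the group mean with a bar of 1 SD. Insr was low in the 3 LIRKO groups, and Foxo1 was low in Z LIRKO F1KO only.

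The Z and WT groups were compared for the effect of the hemizygous transgene. Per1, a core gene of the circadian clock, was 14.2-fold higher in Z, rising from 2.53 ± 0.73 log2 CPM (SD, n = 3) in WT to 6.37 ± 0.58 log2 CPM (SD, n = 5). The change was 3.83 ± 0.44 log2 units (SE, adjusted p = 6.06e-06) by limma. The non-coding RNA Snhg11 (3.35 ± 0.44, adjusted p = 3.44e-05), Ttc39a (3.35 ± 0.48, adjusted p = 1.03e-04), Lrtm1 (3.34 ± 0.53, adjusted p = 2.85e-04) and the deubiquitinase gene Usp2 (3.07 ± 0.65, adjusted p = 0.00322) also rose. Cish, which encodes a feedback inhibitor of cytokine receptors (-3.69 ± 0.54, adjusted p = 1.14e-04), and E2f8, a transcription factor of hepatocyte polyploidy (-3.37 ± 0.55, adjusted p = 3.49e-04), fell. Phlda1 (-2.93 ± 0.49, adjusted p = 3.96e-04), the mitochondrial carrier gene Slc25a30 (-2.71 ± 0.56, adjusted p = 0.00274) and Onecut1, a hepatocyte transcription factor (-2.59 ± 0.73, adjusted p = 0.0232), fell too. With the clock value as a covariate Usp2 (1.15), Slc25a30 (-2.46) and Onecut1 (-2.17) did not pass. Without the Prss2 libraries Ttc39a (1.64), Lrtm1 (1.91), E2f8 (-2.42), Slc25a30 (-1.79) and Onecut1 (-2.56) did not. Usp2 was also lost with voom weights (3.03) and Onecut1 with Zstar in place of Z (-1.36), among 8 alternatives. In all, 1418 of 13596 genes passed, 801 of them higher in Z and 617 lower.

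Genes of the unfolded protein response, which handles misfolded protein in the endoplasmic reticulum, were higher in Z. Of 30 measured, 12 rose, 1 fell and 17 did not pass (21 rose and 1 fell over the list alone), with camera adjusted p = 2.37e-09, estimated 0.594 (the latter with a correlation estimated from the data, as below). Herpud1 (1.66 ± 0.27, adjusted p = 3.01e-04) and Derl3 (2.58 ± 0.49, adjusted p = 0.00135), both of endoplasmic reticulum-associated degradation, and the disulfide isomerase gene Pdia6 (0.76 ± 0.16, adjusted p = 0.0027) rose. Xbp1, a transcription factor of this response, fell (-0.89 ± 0.18, adjusted p = 0.00304). It did not pass with Zstar in place of Z (-0.51), with the clock value as a covariate (-0.79) or without the Prss2 libraries (-0.66). Pdia6 did not in a fit of the 2 groups alone (0.76). Among FOXO1-activated and gluconeogenic genes 5 rose, 1 fell and 13 did not pass (6 rose and 1 fell over the list alone), with camera adjusted p = 0.042, estimated 1. Pck1, a gluconeogenic enzyme gene, rose by 1.67 ± 0.24 log2 units (SE, adjusted p = 1.04e-04). Of NRF2 targets, genes of the oxidative stress response, 5 rose and 15 did not pass (5 rose over the list alone), with camera adjusted p = 0.00275, estimated 0.847. Srxn1 (0.89 ± 0.20, adjusted p = 0.00434) and Gpx2 (3.01 ± 0.83, adjusted p = 0.0209) rose. Srxn1 did not pass with the clock value as a covariate (0.77). Gpx2 did not with log2(CPM + 1) (0.37), with Zstar in place of Z or in 5 other alternatives. In the growth hormone and IGF axis 1 rose, 5 fell and 8 did not pass (1 rose and 5 fell over the list alone), with camera adjusted p = 0.042, estimated 0.594. Its falling members included Socs2, a feedback inhibitor of growth hormone signalling (-2.38 ± 0.57, adjusted p = 0.00861), and the leptin receptor gene Lepr (-1.83 ± 0.35, adjusted p = 0.00163). Socs2 did not pass without the Prss2 libraries (-2.23), with the clock covariate (-1.87) or without WT mouse 1586 (-1.97). Lepr stood at 5.45 log2 CPM in WT mouse 1564 of this table, against 3.34 and 2.69 in the other WT mice. Without mouse 1564 its change was -1.02 (adjusted p = 0.00894, limma), and in a fit of the 2 groups alone Lepr did not pass (adjusted p = 0.0596). In the homozygous table WT mice 1564, 1586 and 1601 stood at 1.95, 2.61 and 2.16 log2 CPM. The ZZ mice there, at 1.38, 2.25 and 2.47, overlapped them, so a fall of Lepr with the transgene is uncertain. Targets of PPARA and fatty acid oxidation genes were lower: 4 fell and 24 did not pass (4 fell over the list alone), with camera adjusted p = 0.0057, estimated 1. No mouse Serpina1 gene passed, from Serpina1e (-2.05 ± 0.81, adjusted p = 0.109) to Serpina1c (0.04 ± 0.20, adjusted p = 0.93). Serpina1c did pass with Zstar in place of Z (0.67), and Serpina1e without the Prss2 libraries (-4.42), where mouse 1564 was the only WT mouse. Serpina1e stood at -0.95 without that mouse and at -0.18 with Zstar in place of Z, and did not pass.

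Clock genes moved with this comparison. Of 19 measured, 6 rose and 13 did not pass (10 rose and 4 fell over the list alone), with camera adjusted p = 0.0244, estimated 0.847. A clock value per library, the mean of 5 genes of the late phase (Dbp, Tef, Per3, Nr1d2, Hlf) minus that of 5 genes of the early phase (Arntl, Npas2, Clock, Cry1, Nfil3), averaged 2.39 ± 1.55 (SD, n = 5) in Z and 0.29 ± 1.12 (SD, n = 3) in WT. Pancreatic transcripts were also uneven, with a mean over 9 genes of 1.87 ± 5.40 (SD, n = 3) log2 CPM in WT and -2.85 ± 2.15 (SD, n = 5) in Z. None of the 11 measured pancreas, fat and muscle markers passed, over all genes or over the list alone (camera adjusted p = 0.0152, estimated 1). With the clock value as a covariate 300 genes passed, and 569 without the Prss2 libraries, which left only WT mouse 1564, assumed to vary like the other groups. With WT mouse 1564 or 1586 left out 880 or 879 passed. With Zstar in place of Z 2181 genes passed.

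**Figure D2:**
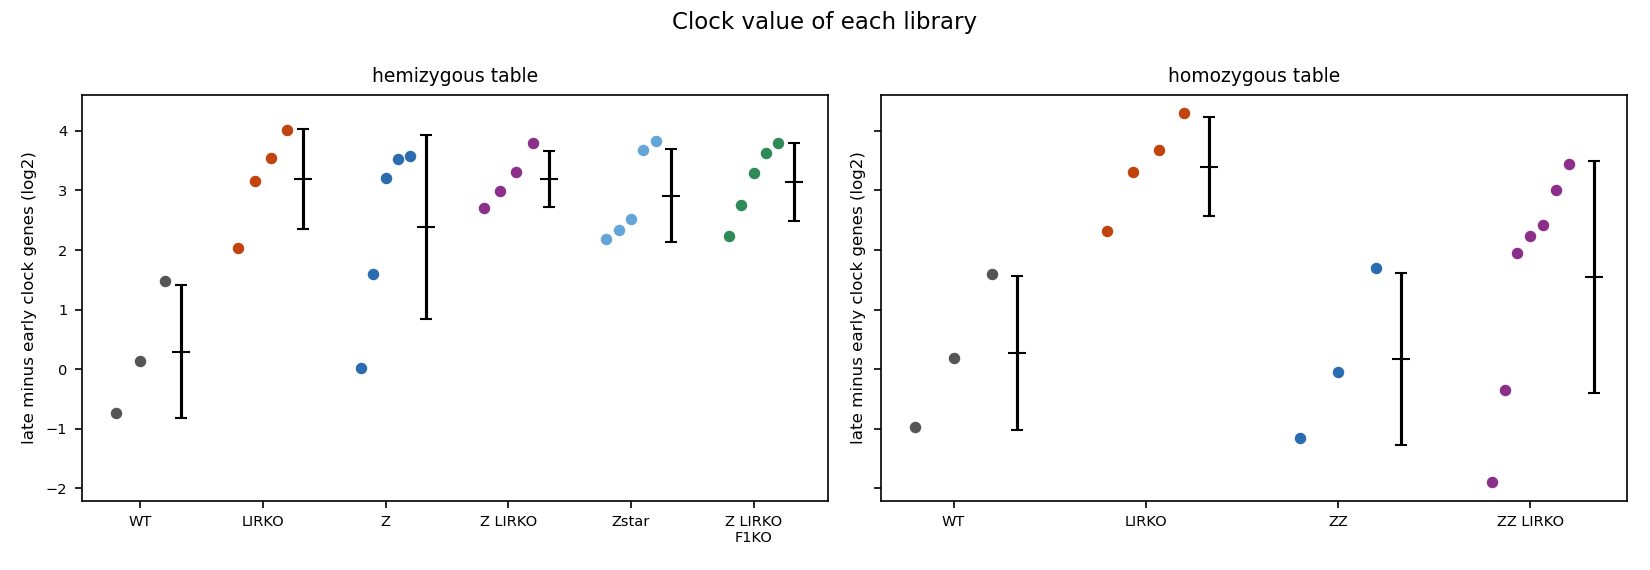
Clock value of each library (mean of 5 late-phase genes minus mean of 5 early-phase genes, log2 units) by group, with 1 point per mouse, the group mean and a bar of 1 SD, in the hemizygous table (left) and the homozygous table (right). WT libraries lay between -0.73 and 1.48 in the hemizygous table, LIRKO libraries between 2.04 and 4.01, and the ZZ LIRKO libraries spread from -1.90 to 3.45.

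LIRKO was compared with WT for the effect of insulin receptor loss without the transgene. Lepr, the leptin receptor gene (chromosome 4, 101717404 to 101815352), was 48.9-fold higher (5.61 ± 0.37, adjusted p = 3.47e-10, limma). H19, an imprinted non-coding RNA (6.20 ± 1.03, adjusted p = 1.05e-04), the glycogen-targeting phosphatase subunit gene Ppp1r3g (5.77 ± 1.16, adjusted p = 7.93e-04) and the anion exchanger gene Slc4a9 (5.73 ± 0.54, adjusted p = 8.28e-08) rose. Without WT mouse 1564 these 4 changes were 6.43, 6.83, 6.70 and 6.35. Ppp1r3g did not pass with the clock value as a covariate (3.60) or without the Prss2 libraries (3.91). The fatty acid elongase gene Elovl3 (-7.24 ± 0.90, adjusted p = 3.32e-06), the steroid dehydrogenase gene Hsd3b5 (-5.75 ± 0.83, adjusted p = 1.91e-05), the bile acid transporter gene Slc10a2 (-5.42 ± 0.43, adjusted p = 5.39e-09) and the major urinary protein gene Mup3 (-5.42 ± 0.56, adjusted p = 2.55e-07) fell. In all, 3229 genes passed, 1598 higher and 1631 lower.

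Sex-biased genes moved together in these male livers. Of 23 measured male-biased genes 16 fell and 7 did not pass (19 fell over the list alone), with camera adjusted p = 5.96e-13, estimated 0.355. Cyp4a12a, a fatty acid hydroxylase gene (-4.26 ± 0.44, adjusted p = 2.74e-07), and Mup20 (-3.67 ± 0.39, adjusted p = 3.14e-07) fell. Of 19 female-biased genes 11 rose and 8 did not pass (12 rose over the list alone), with camera adjusted p = 1.04e-06, estimated 0.355. The transcription factor gene Cux2 (4.32 ± 0.52, adjusted p = 2.28e-06) and Cyp2b10 (4.28 ± 0.58, adjusted p = 9.55e-06) rose. In the growth hormone and IGF axis, 4 genes rose and 4 fell (4 and 5 over the list alone), and the camera adjusted p was 0.934. Igfbp2 (3.01 ± 0.20, adjusted p = 3.47e-10) rose. Igf1 (-1.70 ± 0.20, adjusted p = 1.10e-06), the acid-labile subunit gene Igfals (-2.57 ± 0.27, adjusted p = 2.55e-07) and the growth hormone receptor gene Ghr (-1.25 ± 0.16, adjusted p = 4.36e-06) fell.

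FOXO1-activated and gluconeogenic genes were higher in LIRKO. Of them 9 rose, 2 fell and 8 did not pass (12 rose and 2 fell over the list alone), with camera adjusted p = 0.00103, estimated 0.583. Igfbp1, a FOXO1-induced binding protein of IGFs (5.20 ± 0.65, adjusted p = 3.71e-06), Irs2, an adaptor of the insulin receptor (2.80 ± 0.41, adjusted p = 2.60e-05), Pck1 (1.90 ± 0.25, adjusted p = 7.46e-06) and the coactivator gene Ppargc1a (2.38 ± 0.34, adjusted p = 1.75e-05) rose. Without WT mouse 1564 Igfbp1 stood at 6.04. Cholesterol synthesis genes were lower: 10 fell and 15 did not pass (16 fell over the list alone), with camera adjusted p = 1.66e-05, estimated 0.748. Mvd (-2.25 ± 0.49, adjusted p = 0.00167) and Idi1 (-1.84 ± 0.48, adjusted p = 0.00681) fell, but did not pass without the Prss2 libraries (-1.48 and -1.28). Unfolded protein response genes were lower as well. For these 2 rose, 14 fell and 14 did not pass (2 rose and 16 fell over the list alone), with camera adjusted p = 2.41e-04, estimated 0.748. The chaperone gene Hspa5 (-1.14 ± 0.26, adjusted p = 0.00268) and the degradation adaptor gene Sel1l (-0.98 ± 0.15, adjusted p = 6.02e-05) fell. Without WT mouse 1586 Hspa5 stood at -0.65. Fetal and liver tumour markers were higher (6 rose and 8 did not pass (8 rose over the list alone), camera adjusted p = 2.41e-04, estimated 0.368), as were cell cycle genes (8 rose, 1 fell and 15 did not pass (12 rose and 2 fell over the list alone), camera adjusted p = 0.0047, estimated 0.748). Igf2bp3 (5.09 ± 0.60, adjusted p = 1.52e-06) and the cyclin D1 gene Ccnd1 (1.96 ± 0.35, adjusted p = 2.68e-04) rose. Serpina1c (-1.16 ± 0.21, adjusted p = 2.67e-04) and Serpina1e (-3.92 ± 0.85, adjusted p = 0.00153), mouse alpha-1-antitrypsin genes, fell. Serpina1e did not pass with the clock covariate (-2.76). Endothelial markers were higher (3 rose and 13 did not pass (4 rose over the list alone), camera adjusted p = 0.017, estimated 0.748), as were stellate cell and matrix markers (4 rose and 18 did not pass (4 rose over the list alone), camera adjusted p = 0.035, estimated 0.787).

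The same 7 mice gave 3803 genes in the homozygous table, 1890 higher and 1913 lower. Fold changes of the 13044 genes tested in both tables had a Spearman correlation of 0.887 across genes, which are not independent replicates. Lepr rose there by 7.06 ± 0.25 log2 units (SE, adjusted p = 3.48e-11), H19 by 8.82 ± 1.30 and Igfbp1 by 6.47 ± 0.43 (limma, adjusted p = 1.64e-04 and 6.70e-08). H19 did not pass there with voom weights (8.90). Of male-biased genes 14 fell and 8 did not pass (16 fell over the list alone) there, with camera adjusted p = 1.32e-08, estimated 0.722. Of female-biased genes 12 rose and 10 did not pass (12 rose over the list alone), with camera adjusted p = 6.80e-06, estimated 0.699. Macrophage and monocyte markers were higher there (10 rose and 12 did not pass (11 rose over the list alone), camera adjusted p = 0.00326, estimated 0.722), as were endothelial markers (5 rose and 11 did not pass (6 rose over the list alone), camera adjusted p = 0.00687, estimated 0.722). The clock value averaged 3.19 ± 0.84 (SD, n = 4) in LIRKO and 0.29 ± 1.12 (SD, n = 3) in WT of the hemizygous table. Pancreas, fat and muscle markers were lower in LIRKO there (3 fell and 8 did not pass (8 fell over the list alone), camera adjusted p = 0.00428, estimated 0.748). With the clock value as a covariate 1511 genes passed in the hemizygous table. Without the Prss2 libraries, with only WT mouse 1564 left, 1218 passed there and 1707 in the homozygous table.

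Z LIRKO was compared with Z for the effect of insulin receptor loss in the presence of the transgene. Lepr was the gene with the largest rise among those the naming rule took, from 2.00 ± 0.37 log2 CPM (SD, n = 5) to 9.22 ± 0.08 log2 CPM (SD, n = 4). Its change was 7.22 ± 0.33 log2 units (SE, adjusted p = 1.47e-13) by limma. Slc4a9 (5.65 ± 0.48, adjusted p = 5.51e-09), the tubulin gene Tuba8 (4.91 ± 0.51, adjusted p = 1.53e-07) and H19 (4.43 ± 0.90, adjusted p = 6.04e-04) rose. Elovl3 (-7.31 ± 0.79, adjusted p = 2.74e-07), Hsd3b5 (-6.13 ± 0.73, adjusted p = 9.66e-07), Cyp4a12a (-6.12 ± 0.39, adjusted p = 6.63e-11), Slc10a2 (-5.70 ± 0.37, adjusted p = 1.10e-10) and the sarcomere gene Myom2 (-5.70 ± 0.47, adjusted p = 3.30e-09) fell. In all, 4669 genes passed, 2268 higher and 2401 lower. Without the Prss2 libraries 3092 did.

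Unfolded protein response genes were lower in Z LIRKO than in Z. The Z mice also enter Z against WT, which favours opposite directions there by chance alone. Of 30, 20 fell and 10 did not pass (21 fell over the list alone), with camera adjusted p = 8.18e-07, estimated 0.587. Derl3 (-3.63 ± 0.45, adjusted p = 1.67e-06), Herpud1 (-1.29 ± 0.24, adjusted p = 3.11e-04), Pdia6 (-0.86 ± 0.14, adjusted p = 7.56e-05) and Sel1l (-1.04 ± 0.14, adjusted p = 3.96e-06) fell. Male-biased genes were lower (21 fell and 2 did not pass (21 fell over the list alone), camera adjusted p = 1.79e-16, estimated 0.26). Female-biased genes were higher (12 rose and 7 did not pass (13 rose over the list alone), camera adjusted p = 1.07e-06, estimated 0.26). Cholesterol synthesis genes were lower (15 fell and 10 did not pass (15 fell over the list alone), camera adjusted p = 3.21e-05, estimated 0.596). The farnesyl diphosphate synthase gene Fdps fell (-1.71 ± 0.36, adjusted p = 9.34e-04). Fatty acid and triglyceride synthesis genes were lower as well (9 fell and 11 did not pass (2 rose and 10 fell over the list alone), camera adjusted p = 0.0226, estimated 0.596). The desaturase gene Scd1 (-2.54 ± 0.59, adjusted p = 0.00186) and the lipogenic regulator gene Thrsp (-3.63 ± 0.56, adjusted p = 2.96e-05) fell. Among FOXO1-activated and gluconeogenic genes 7 rose, 1 fell and 11 did not pass (8 rose and 1 fell over the list alone), with camera adjusted p = 0.0311, estimated 0.596. Igfbp1 (3.65 ± 0.57, adjusted p = 3.84e-05) and Irs2 (2.63 ± 0.36, adjusted p = 7.19e-06) rose. Serpina1c (-1.61 ± 0.18, adjusted p = 5.64e-07) and Serpina1e (-2.95 ± 0.74, adjusted p = 0.00379) fell. Fdps (-1.13) and Serpina1e (-2.75) did not pass without the Prss2 libraries.

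Markers of 4 other cell types were higher in Z LIRKO, while cholangiocyte, neutrophil and red cell markers had no call. Of the endothelial markers 15 rose and 1 did not pass (16 rose over the list alone), with camera adjusted p = 4.00e-06, estimated 0.587. Bmp2, a ligand gene of sinusoidal endothelium, rose by 0.96 ± 0.16 log2 units (SE, adjusted p = 6.18e-05). Of the macrophage and monocyte markers 10 rose and 12 did not pass (13 rose over the list alone), with camera adjusted p = 7.52e-05, estimated 0.596. The scavenger receptor gene Marco (3.03 ± 0.48, adjusted p = 4.60e-05) rose. Of the lymphocyte markers 11 rose and 5 did not pass (13 rose over the list alone), with camera adjusted p = 6.65e-05, estimated 0.52. The IgM heavy chain gene Ighm (1.38 ± 0.28, adjusted p = 5.28e-04) rose. Of the stellate cell and matrix markers 11 rose and 11 did not pass (11 rose over the list alone), with camera adjusted p = 3.07e-04, estimated 0.596. Of the cell cycle genes 14 rose, 2 fell and 8 did not pass (14 rose and 2 fell over the list alone), with camera adjusted p = 4.45e-04, estimated 0.596. Ccnd1 (2.74 ± 0.31, adjusted p = 5.04e-07) rose. Pancreatic transcripts averaged -0.89 ± 4.21 (SD, n = 4) log2 CPM in Z LIRKO and -2.85 ± 2.15 (SD, n = 5) in Z.

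The 2 effects of insulin receptor loss, measured in separate mice with and without the transgene, were set side by side. Of the genes tested, 1058 were higher in both, against 267 for independent lists. In turn 1158 were lower in both, against 288. Fold changes correlated across genes with a Spearman coefficient of 0.694. Their difference, the interaction of LIRKO and Z, passed for 27 genes, 8 with a larger and 19 with a smaller value in the presence of the transgene. Timeless, of replication fork protection (1.72 ± 0.29, adjusted p = 0.0234), Rassf4 (1.55 ± 0.28, adjusted p = 0.0283) and Rgs3, a regulator of G protein signalling (1.50 ± 0.32, adjusted p = 0.0466), had larger values. Per1 (-3.04 ± 0.61, adjusted p = 0.0349), Adam11 (-2.38 ± 0.40, adjusted p = 0.0234) and Rarres1 (-1.82 ± 0.39, adjusted p = 0.0466) had smaller values by limma. None of these 6 passed with the clock value as a covariate, at 1.44, 1.46, 1.34, -2.06, -2.31 and -1.46, so most stayed about as large. Of the clock genes in the interaction 1 fell and 18 did not pass (2 fell over the list alone), with camera adjusted p = 0.00317, estimated 0.557. No gene at all passed by limma in that fit, while 824 had an unadjusted p under 0.05. Pancreas, fat and muscle markers had higher values (camera adjusted p = 9.48e-07, estimated 0.557), although none of the 11 passed over all genes and 8 did over the list alone. The count of 27 was the least stable of the comparisons. By limma 0 genes passed without Z mouse 1442 or LIRKO mouse 1468 (1154 and 1171 at an unadjusted p under 0.05). There were 50 without Z mouse 1410.

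Z LIRKO F1KO was compared with Zstar, the PiZ mice of the same source name, for the joint effect of losing the insulin receptor and FOXO1. Macrophage and monocyte markers were higher: 18 rose and 4 did not pass (20 rose over the list alone), with camera adjusted p = 6.52e-14, estimated 0.311. Marco rose by 3.35 ± 0.46 log2 units (SE, adjusted p = 1.88e-05). The Kupffer cell genes Vsig4 (1.10 ± 0.11, adjusted p = 4.82e-07), Clec4f (0.91 ± 0.10, adjusted p = 2.00e-06) and Cd5l (1.23 ± 0.14, adjusted p = 1.63e-06) rose too. Mice 201, 206 and 207 stood apart from 169 and 170 of this group, seen after the results. Their Gpnmb was 3.67, 2.20 and 4.36 log2 CPM against -1.60 and -0.27, and their Col1a1 4.89, 3.82 and 4.82 against 2.66 and 2.93. Elovl3 and Igfbp1 split these mice too, and the cause was not tested. The peroxisomal transporter gene Abcd2 (3.43 ± 0.52, adjusted p = 5.95e-05), Lepr (2.72 ± 0.31, adjusted p = 1.76e-06), Ccnd1 (2.51 ± 0.29, adjusted p = 2.91e-06) and BC089597 (2.28 ± 0.23, adjusted p = 5.24e-07) were among the largest rises. Serpina12, which encodes the adipokine vaspin (-4.94 ± 0.48, adjusted p = 3.18e-07), the water channel gene Aqp4 (-4.02 ± 0.41, adjusted p = 4.82e-07), Clic5 (-3.91 ± 0.51, adjusted p = 1.27e-05), the calpain gene Capn8 (-3.43 ± 0.65, adjusted p = 5.68e-04) and the complement gene C4a (-3.37 ± 0.38, adjusted p = 1.58e-06) fell. In all, 3196 genes passed, 1685 higher and 1511 lower.

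Cell cycle genes were higher in this comparison too (16 rose and 8 did not pass (20 rose over the list alone), camera adjusted p = 9.01e-08, estimated 0.406). Top2a, a topoisomerase gene of dividing cells, rose (1.52 ± 0.32, adjusted p = 0.00147). Lymphocyte markers were higher (10 rose and 6 did not pass (12 rose and 1 fell over the list alone), camera adjusted p = 5.06e-06, estimated 0.406). The leukocyte gene Ptprc (1.69 ± 0.19, adjusted p = 1.54e-06) rose. Of the NF-kB targets 7 rose and 12 did not pass (11 rose and 1 fell over the list alone), with camera adjusted p = 6.20e-04, estimated 0.464. The adhesion genes Vcam1 (1.64 ± 0.31, adjusted p = 4.76e-04) and Icam1 (0.88 ± 0.19, adjusted p = 0.00157) rose. Male-biased genes were lower (15 fell and 8 did not pass (20 fell over the list alone), camera adjusted p = 8.38e-09, estimated 0.406). Mup20 (-2.67 ± 0.32, adjusted p = 4.17e-06) fell. Of the female-biased genes 5 rose and 14 did not pass (5 rose over the list alone), with camera adjusted p = 0.0352, estimated 0.553. Unfolded protein response genes were lower too (7 fell and 23 did not pass (8 fell over the list alone), camera adjusted p = 0.00195, estimated 0.553). Derl3 (-1.77 ± 0.42, adjusted p = 0.00368) fell. Serpina1c (-1.02 ± 0.17, adjusted p = 1.85e-04) and Serpina1b (-0.49 ± 0.16, adjusted p = 0.0274) fell. Pancreatic transcripts averaged -1.08 ± 4.82 (SD, n = 5) log2 CPM in Z LIRKO F1KO and -2.94 ± 1.86 (SD, n = 5) in Zstar. Without the Prss2 libraries 1692 genes passed, 991 higher and 701 lower. With Z in place of Zstar Abcd2 (0.10), BC089597 (0.37), Capn8 (-1.01), Serpina1b (-0.22) and Serpina1c (-0.39) did not pass.

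The difference between this effect and that of Z LIRKO against Z was tested directly. No PiZ group lost FOXO1 alone, so it also holds the effect of FOXO1 loss itself, as do the ratios below. Slc10a2 (5.55 ± 0.51, adjusted p = 2.45e-07), Elovl3 (5.19 ± 1.09, adjusted p = 0.00451), Tcf24 (5.62 ± 0.76, adjusted p = 4.48e-05) and the organic anion transporter-family gene Slc22a28 (4.60 ± 0.54, adjusted p = 8.30e-06) had larger values in Z LIRKO F1KO against Zstar by limma. Lepr (-4.50 ± 0.45, adjusted p = 8.39e-07), the protease inhibitor gene Serpinb1a (-4.26 ± 0.66, adjusted p = 2.59e-04), Tbc1d30 (-3.83 ± 0.34, adjusted p = 2.00e-07) and Olig1 (-3.53 ± 0.91, adjusted p = 0.0207) had smaller values. Elovl3 did not pass with voom weights (5.14), nor Olig1 without the Prss2 libraries (-2.84) or Z LIRKO mouse 1428 (-3.33). In all, 901 genes passed, 445 with a larger and 456 with a smaller value.

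In this difference the FOXO1-activated and gluconeogenic genes had smaller values, with 3 of 19 past the threshold and 6 over the list alone (camera adjusted p = 0.00167, estimated 0.836). Irs2 (-2.54 ± 0.50, adjusted p = 0.00265) and Sesn3 (-1.37 ± 0.22, adjusted p = 3.17e-04) had smaller values. Igfbp1 did not pass (-2.47 ± 0.79, adjusted p = 0.058) but did with library weights (-2.32), and its direct change from Z LIRKO was -3.93. Male-biased genes had larger values in 10 cases and a smaller value in 1 of 23, against 12 and 1 over the list alone (camera adjusted p = 1.01e-07, estimated 0.836). Cyp4a12a (4.52 ± 0.54, adjusted p = 9.83e-06) had the smallest p. Female-biased genes had smaller values in 5 of 19, and in 8 over the list alone (camera adjusted p = 2.10e-04, estimated 0.836). Cux2 had a smaller value (-4.13 ± 0.63, adjusted p = 2.32e-04), lost with voom weights (-4.13). In the growth hormone axis Igfbp2 (-2.31 ± 0.24, adjusted p = 1.34e-06) had a smaller value while Igf1 (1.53 ± 0.24, adjusted p = 2.42e-04) and Ghr (1.08 ± 0.19, adjusted p = 0.00106) had larger ones. Cholesterol synthesis genes had larger values in 2 of 25, and in 3 over the list alone (camera adjusted p = 2.10e-04, estimated 0.964). No unfolded protein response gene passed in the difference, over all genes or over the list alone (camera adjusted p = 0.00253, estimated 0.964), with Derl3 at 1.86 ± 0.61 (adjusted p = 0.0689). Derl3 passed with library weights (1.95) and in the direct comparison (1.81). Macrophage and monocyte markers had larger values in 2 of 22, and in 2 over the list alone (camera adjusted p = 0.00253, estimated 0.964). They were Lyz2 (1.24 ± 0.35, adjusted p = 0.034) and Vsig4 (0.54 ± 0.16, adjusted p = 0.0486). Leaving out single mice, Lyz2 lost its call in 9 and Vsig4 in 14 of 19 fits. They stood at 0.79 and 0.38 without the Prss2 libraries, and Vsig4 directly at 0.30, none passing. The difference passed for 535 genes without Z LIRKO 1428, 344 without the Prss2 libraries (1428 included) and 1890 with library weights.

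To size this over genes chosen in other mice, the genes called in ZZ LIRKO against ZZ were followed. Among the 1701 genes higher there, the median change was 0.39 in Z LIRKO against Z and 0.08 in Z LIRKO F1KO against Zstar, a ratio of 21.1%. The difference itself passed with a smaller effect for 258 of them and with a larger effect for 10. Among the 1775 genes lower there, the medians were -0.42 and -0.15, a ratio of 37.0%. The difference passed with a smaller effect for 248 and a larger effect for 6. For genes picked in LIRKO against WT the ratios were 39.9% (higher) and 46.6% (lower). Across all genes tested, the 2 effects still correlated (Spearman coefficient of 0.553). There were 931 genes higher in both against 281 for independent lists and 773 lower in both against 267.

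Zstar and Z differ in their labels by an asterisk, which the sources used here do not explain, and by source name. Of 13596 genes, 1288 passed, 594 higher and 694 lower in Zstar. Moxd1 (7.26 ± 1.38, adjusted p = 0.00173), Mup9 (5.35 ± 1.28, adjusted p = 0.00993) and Mup16 (4.07 ± 1.26, adjusted p = 0.0417) had the largest rises by limma under the naming rule. Mup11 (-4.79 ± 0.90, adjusted p = 0.00146), Mme, which encodes neprilysin (-4.08 ± 0.45, adjusted p = 2.46e-06), and the PPARA target Cyp4a14 (-4.05 ± 0.87, adjusted p = 0.00462) had the largest falls. Coagulation and complement genes were higher (6 rose and 19 did not pass (8 rose over the list alone), camera adjusted p = 5.75e-05, estimated 0.923). C9 (1.43 ± 0.27, adjusted p = 0.00135) rose. PPARA targets were lower (7 fell and 21 did not pass (8 fell over the list alone), camera adjusted p = 0.00361, estimated 0.923). The pantetheinase gene Vnn1 (-4.04 ± 0.76, adjusted p = 0.00147) fell. Female-biased genes were lower (5 fell and 14 did not pass (6 fell over the list alone), camera adjusted p = 0.0168, estimated 0.923). Abcd2 (-3.33 ± 0.52, adjusted p = 2.61e-04) fell. Moxd1 (7.19) and Vnn1 (-4.12) did not pass with voom weights, nor Mup16 in 8 of 10 fits without 1 mouse (3.35 to 4.34). Z LIRKO F1KO mice share the source name of Zstar, so a direct comparison with Z LIRKO, in which 3062 genes passed, held this difference as well. Mup genes are near-identical paralogs, so reads can be split unevenly between them.

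ZZ was compared with WT for the effect of the homozygous transgene. Matrix genes of stellate cells and fibroblasts rose nearly throughout: of 23 markers 22 rose and 1 did not pass (22 rose over the list alone), with camera adjusted p = 1.80e-15, estimated 0.133. Col1a1, the main chain of type I collagen, rose by 3.96 ± 0.41 log2 units (SE, adjusted p = 5.66e-06). The collagen cross-linking gene Lox rose by 3.88 ± 0.41 and the matrix protease gene Mmp2 by 2.94 ± 0.29 (limma, adjusted p = 6.36e-06 and 3.46e-06). Ly6d (7.28 ± 0.83, adjusted p = 1.34e-05), the serpin gene Serpina3f (6.53 ± 0.29, adjusted p = 6.06e-10), the lipocalin 2 gene Lcn2 (4.89 ± 0.56, adjusted p = 1.26e-05), Cyp2a4 (4.56 ± 0.85, adjusted p = 8.44e-04) and the efflux pump gene Abcc4 (4.49 ± 0.33, adjusted p = 1.87e-07) rose. Cyp17a1, a steroid hydroxylase gene (-3.76 ± 0.96, adjusted p = 0.00748), Elovl3 (-3.56 ± 1.12, adjusted p = 0.0247), E2f8 (-3.03 ± 0.80, adjusted p = 0.00897), the lysophospholipid transporter gene Mfsd2a (-2.78 ± 0.62, adjusted p = 0.00302) and the thioesterase gene Acot1 (-2.60 ± 0.56, adjusted p = 0.00241) fell. In all, 4149 of 13690 genes passed, 2205 higher and 1944 lower.

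NRF2 targets were higher in ZZ: 12 rose and 8 did not pass (12 rose over the list alone), with camera adjusted p = 1.19e-08, estimated 0.124. The cystine transporter gene Slc7a11 (9.40 ± 0.59, adjusted p = 4.05e-08), the carbonyl reductase gene Cbr3 (4.34 ± 0.26, adjusted p = 2.58e-08) and Srxn1 (2.46 ± 0.17, adjusted p = 1.41e-07) rose. Of the cholangiocyte markers 9 rose and 3 did not pass (10 rose over the list alone), with camera adjusted p = 5.29e-06, estimated 0.124. The epithelial adhesion gene Epcam (2.92 ± 0.32, adjusted p = 8.06e-06) and the osteopontin gene Spp1 (2.91 ± 0.36, adjusted p = 3.08e-05) rose. Of the macrophage and monocyte markers 15 rose, 2 fell and 5 did not pass (15 rose and 2 fell over the list alone), with camera adjusted p = 2.81e-07, estimated 0.221. Gpnmb (7.77 ± 0.46, adjusted p = 2.57e-08) and Trem2 (5.13 ± 0.61, adjusted p = 2.13e-05), genes of lipid-handling macrophages, rose. Of the neutrophil markers 4 rose and 1 did not pass (4 rose over the list alone), with camera adjusted p = 0.00105, estimated 0.215. Retnlg rose (6.26 ± 0.83, adjusted p = 5.09e-05). Of the NF-kB targets 10 rose and 9 did not pass (13 rose over the list alone), with camera adjusted p = 1.80e-05, estimated 0.221. The NF-kB subunit gene Relb (2.28 ± 0.30, adjusted p = 4.30e-05) rose. Of the interferon response genes 10 rose, 1 fell and 12 did not pass (11 rose and 1 fell over the list alone), with camera adjusted p = 5.16e-04, estimated 0.486. Oas1a (1.77 ± 0.21, adjusted p = 1.75e-05) rose.

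Cell cycle genes were higher in ZZ (13 rose and 12 did not pass (17 rose over the list alone), camera adjusted p = 6.75e-06, estimated 0.315). The proliferation marker gene Mki67 (2.50 ± 0.37, adjusted p = 1.33e-04) rose. Of the fetal and liver tumour markers 10 rose and 6 did not pass (11 rose over the list alone), with camera adjusted p = 1.77e-06, estimated 0.173. The galectin gene Lgals3 (3.16 ± 0.27, adjusted p = 1.40e-06) and Sox4 (3.57 ± 0.34, adjusted p = 3.05e-06) rose. Cd24a is held by this list and by the cholangiocyte list (2.67 ± 0.24, adjusted p = 2.12e-06). Of the PPARA targets and fatty acid oxidation genes 15 fell and 13 did not pass (16 fell over the list alone), with camera adjusted p = 1.80e-05, estimated 0.425. Ppara itself (-1.27 ± 0.27, adjusted p = 0.00205) and Cpt2 (-0.83 ± 0.14, adjusted p = 3.03e-04) fell. Of the coagulation and complement genes 9 fell and 16 did not pass (11 fell over the list alone), with camera adjusted p = 5.16e-04, estimated 0.315. Of the bile acid genes 6 fell and 17 did not pass (5 fell over the list alone), with camera adjusted p = 0.00633, estimated 0.173. The bile acid importer gene Slc10a1 (-1.28 ± 0.20, adjusted p = 1.86e-04) fell. Serpina1d (-1.47 ± 0.40, adjusted p = 0.0114), Serpina1a (-0.99 ± 0.29, adjusted p = 0.0169) and Serpina1b (-0.60 ± 0.22, adjusted p = 0.0476) fell. Of 30 unfolded protein response genes 7 rose, 1 fell and 22 did not pass (7 rose and 1 fell over the list alone), without a camera call (adjusted p = 0.137). Trib3 (3.11 ± 0.30, adjusted p = 3.13e-06), Atf3 (3.66 ± 0.40, adjusted p = 8.79e-06) and the asparagine synthetase gene Asns (4.15 ± 0.83, adjusted p = 0.00146), also induced by other stresses, rose. Without the Prss2 libraries Asns (1.73), Cyp17a1 (-4.68), E2f8 (-2.28), Mfsd2a (-2.48), Acot1 (-1.21), Cpt2 (-0.60) and Serpina1b (-0.90) did not pass. In that fit, with only WT mouse 1564 left, 1964 genes passed. Xbp1 fell (-0.90 ± 0.16, adjusted p = 4.88e-04). Elovl3 did not pass without WT mouse 1564 or ZZ mouse 1809 or 1682, with a change of -2.75, -2.74 or -3.29.

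**Figure D3:**
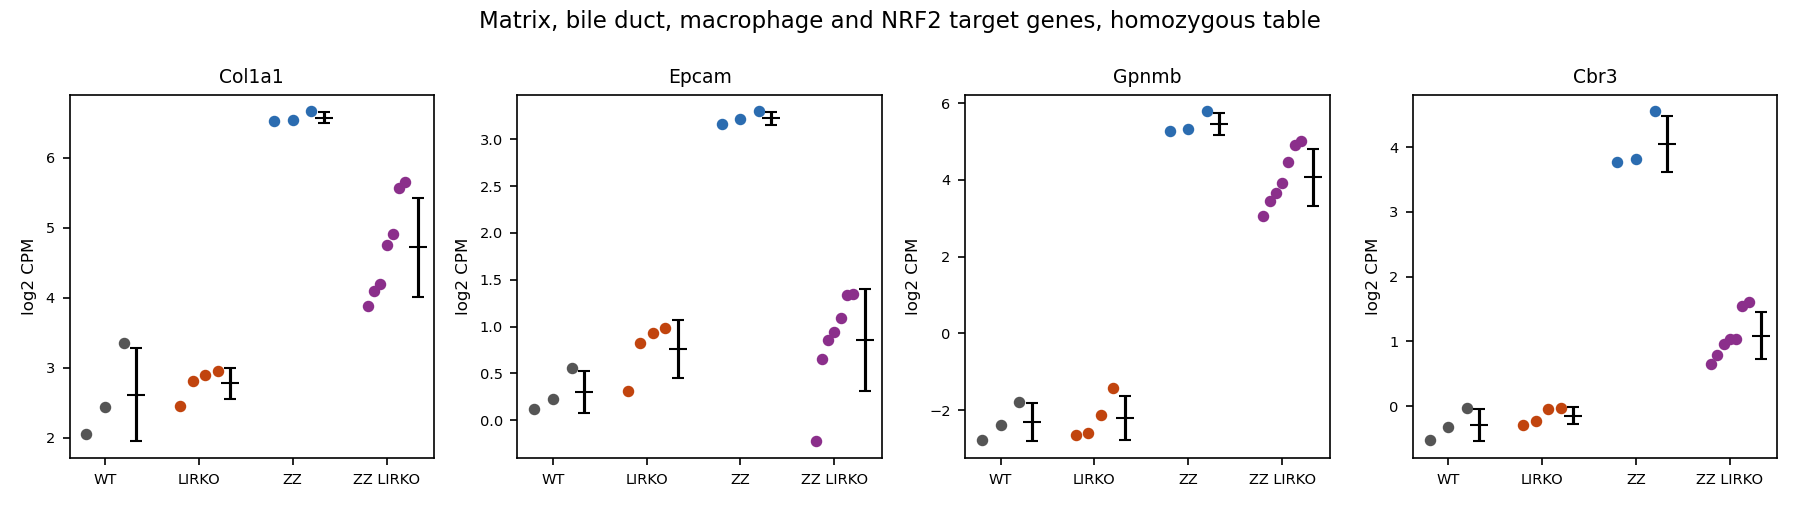
Level of Col1a1, Epcam, Gpnmb and Cbr3 (log2 CPM, vertical axes) in the 4 groups of the homozygous table, with 1 point per mouse and, beside the points, the group mean with a bar of 1 SD. All 4 genes were higher in ZZ than in WT, by 3.96, 2.92, 7.77 and 4.34 log2 units, and Col1a1, Epcam and Cbr3 were lower in ZZ LIRKO than in ZZ.

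The Z and ZZ effects against WT were compared across 13044 genes, with the same WT mice in both. Their Spearman correlation was 0.404, and unchanged groups simulated against those WT mice gave 0.350 on average. The same sign was found for 63.8% of genes, against a mean of 62.8% in the simulations, whose highest value lay above the one found, so this share lay within the range without change. The covariance was 0.195 against 0.0322 simulated, a difference of 0.163. Genes higher in both numbered 296, against 122 for independent lists, and genes lower in both 258, against 88.0. The 3 WT mice cannot be split into groups of 2, so part of this excess can come from the shared WT mice.

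ZZ LIRKO was compared with ZZ for the effect of insulin receptor loss in homozygous PiZ livers. Cholangiocyte markers were lower in ZZ LIRKO: 1 rose, 10 fell and 1 did not pass (1 rose and 10 fell over the list alone), with camera adjusted p = 2.80e-06, estimated 0.0967. Spp1 fell from 7.41 ± 0.17 log2 CPM (SD, n = 3) to 4.56 ± 0.64 log2 CPM (SD, n = 7), a change of -2.86 ± 0.31 log2 units (SE, adjusted p = 1.17e-05) by limma. Epcam (-2.37 ± 0.27, adjusted p = 1.76e-05) and Krt7 (-1.47 ± 0.25, adjusted p = 5.18e-04) fell too. Of the stellate cell and matrix markers 13 fell and 10 did not pass (15 fell over the list alone), with camera adjusted p = 3.82e-06, estimated 0.359. Col1a1 (-1.85 ± 0.35, adjusted p = 0.00103) and Loxl1 (-1.33 ± 0.23, adjusted p = 5.45e-04) fell. Of the NRF2 targets 1 rose, 13 fell and 6 did not pass (1 rose and 14 fell over the list alone), with camera adjusted p = 5.23e-07, estimated 0.122. Cbr3 (-2.96 ± 0.22, adjusted p = 5.97e-07) and Slc7a11 (-3.90 ± 0.50, adjusted p = 5.30e-05) fell. In all, 3666 genes passed, 1811 higher and 1855 lower. The ZZ mice also enter ZZ against WT, which favours opposite directions by chance alone.

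Among the largest rises under the naming rule were those of the sulfotransferase genes Sult2a1 (8.08 ± 1.66, adjusted p = 0.00191) and Sult2a2 (7.27 ± 1.18, adjusted p = 3.32e-04), of Lepr (7.02 ± 0.22, adjusted p = 7.54e-12) and of Cyp17a1 (6.69 ± 0.81, adjusted p = 3.14e-05). Among the largest falls were those of Cyp4a12a (-5.08 ± 0.40, adjusted p = 9.79e-07), Cyp4a12b (-4.88 ± 0.73, adjusted p = 1.75e-04), Mup20 (-4.51 ± 0.60, adjusted p = 6.93e-05) and Snhg11 (-4.41 ± 0.47, adjusted p = 1.13e-05). Cyp4a12a and Cyp4a12b, like Sult2a1 and Sult2a2, are close paralogs whose reads can be exchanged. Neither Sult2a gene passed with voom weights on the recovered reads.

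Of the female-biased genes in ZZ LIRKO against ZZ 14 rose and 8 did not pass (18 rose over the list alone), with camera adjusted p = 4.10e-09, estimated 0.0967. Of the male-biased genes 16 fell and 6 did not pass (18 fell over the list alone), with camera adjusted p = 3.24e-11, estimated 0.153. Of the FOXO1-activated and gluconeogenic genes 10 rose and 9 did not pass (11 rose over the list alone), with camera adjusted p = 3.82e-06, estimated 0.137. Ppargc1a (2.64 ± 0.22, adjusted p = 1.32e-06), Pck1 (1.81 ± 0.23, adjusted p = 4.33e-05) and the gluconeogenic phosphatase gene Fbp1 (0.97 ± 0.13, adjusted p = 6.90e-05) rose. Of the unfolded protein response genes 14 fell and 16 did not pass (19 fell over the list alone), with camera adjusted p = 3.82e-06, estimated 0.398. Chac1 (-2.03 ± 0.38, adjusted p = 9.17e-04) and Sel1l (-0.68 ± 0.15, adjusted p = 0.00359) fell. PPARA targets and fatty acid oxidation genes were higher (12 rose, 1 fell and 15 did not pass (15 rose and 1 fell over the list alone), camera adjusted p = 1.54e-04, estimated 0.554). The carnitine acyltransferase gene Cpt1a (1.22 ± 0.18, adjusted p = 1.57e-04) rose. Endothelial markers were higher (14 rose and 2 did not pass (14 rose over the list alone), camera adjusted p = 5.72e-09, estimated 0.122). The scavenger receptor gene Stab2 (0.73 ± 0.10, adjusted p = 8.03e-05) rose. Serpina1c fell (-1.07 ± 0.26, adjusted p = 0.00662). Serpina1d (1.04 ± 0.34, adjusted p = 0.0317) and Serpina1a (0.70 ± 0.24, adjusted p = 0.0453) rose, but without ZZ mouse 1682 they stood at 0.40 and 0.29 and did not pass. The clock value averaged 1.55 ± 1.94 (SD, n = 7) in ZZ LIRKO and 0.17 ± 1.44 (SD, n = 3) in ZZ.

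The effect of insulin receptor loss in ZZ livers was also set against that in the other mice. With Z LIRKO against Z, measured in separate mice, 849 genes were higher in both (290 for independent lists) and 936 were lower in both (314). The Spearman coefficient across genes was 0.470. With Z LIRKO F1KO against Zstar the coefficient was 0.180, with 340 genes higher in both against 214 and 416 lower in both against 196.

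The interaction of LIRKO and ZZ, the difference between the effect of LIRKO in ZZ and in WT livers, passed for 1061 genes, 415 with a larger and 646 with a smaller value in ZZ. Cholangiocyte markers had smaller values in 7 of 12, and in 8 over the list alone (camera adjusted p = 1.78e-06, estimated 0.0983). Epcam (-2.83 ± 0.40, adjusted p = 0.00103) and Spp1 (-2.86 ± 0.46, adjusted p = 0.00227) had smaller values. Stellate cell and matrix markers had smaller values in 11 of 23, and in 16 over the list alone (camera adjusted p = 4.78e-10, estimated 0.245). Mmp2 (-1.77 ± 0.36, adjusted p = 0.00928) and Fbn1 (-1.27 ± 0.26, adjusted p = 0.00959) had smaller values. NRF2 targets had smaller values in 9 of 20, and in 11 over the list alone (camera adjusted p = 2.58e-09, estimated 0.0983). Abcc4 (-3.92 ± 0.41, adjusted p = 1.71e-04) and Cbr3 (-3.10 ± 0.33, adjusted p = 1.71e-04) had smaller values. Fetal and liver tumour markers had smaller values in 7 of 16, against 8 smaller and 1 larger over the list alone (camera adjusted p = 1.74e-05, estimated 0.245). Macrophage and monocyte markers had smaller values in 4 of 22, and in 5 over the list alone (camera adjusted p = 0.00254, estimated 0.561). Cd14 (-1.72 ± 0.41, adjusted p = 0.0186) had a smaller value. Cyp17a1 (5.80 ± 1.21, adjusted p = 0.00978), Mfsd2a (3.26 ± 0.78, adjusted p = 0.0195) and the lipase inhibitor gene G0s2 (2.84 ± 0.66, adjusted p = 0.0169) had larger values by limma. The nuclear receptor gene Nr4a1 (-4.61 ± 1.18, adjusted p = 0.0273) and Ppp1r3g (-4.33 ± 0.97, adjusted p = 0.0151) had smaller values. With voom weights Nr4a1 (-4.66), Ppp1r3g (-4.25), Cyp17a1 (5.79) and Cd14 (-1.69) did not pass, nor did Ppp1r3g with log2(CPM + 1) (-2.87). The fit without the Prss2 libraries lost these 4 (-3.51, -3.86, 6.73 and -2.06), Mfsd2a (2.96), G0s2 (1.89), Spp1 (-2.51) and Fbn1 (-1.18). The count was 442 without ZZ mouse 1682 and 340 without the Prss2 libraries.

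**Figure D4:**
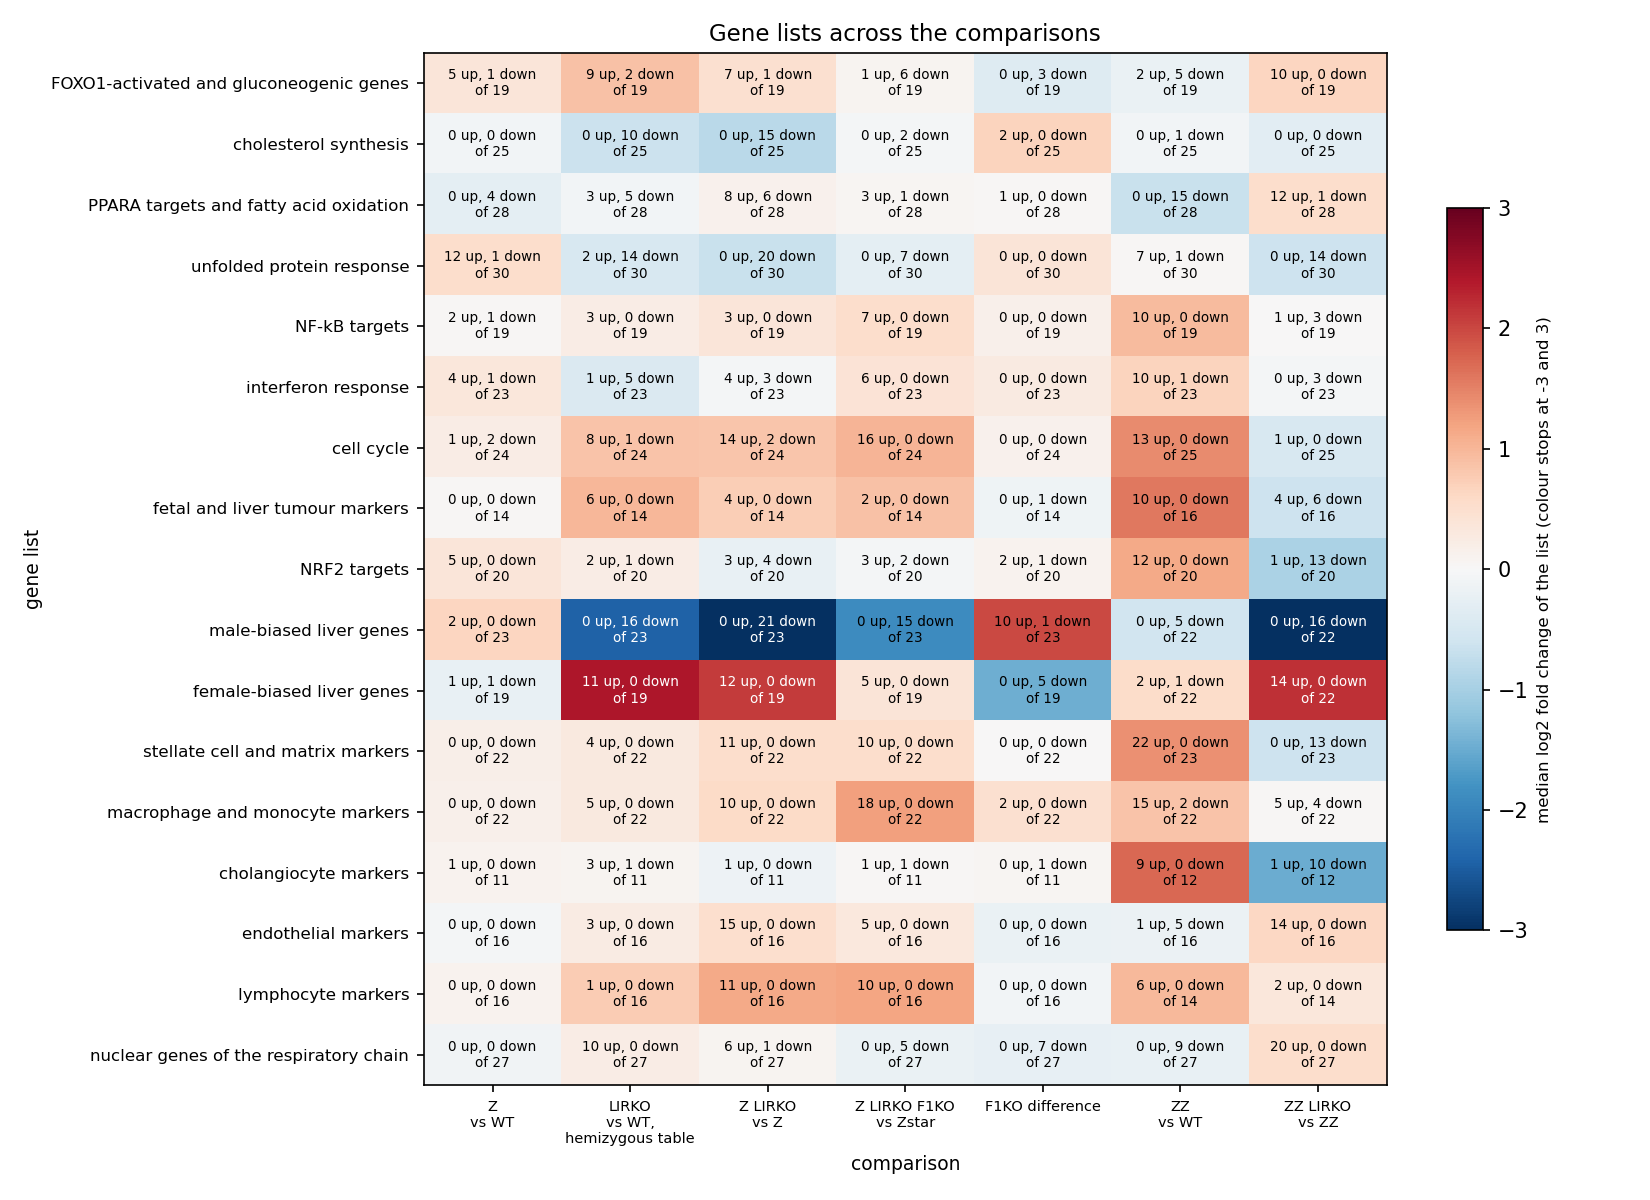
Median log2 fold change (colour, which stops at -3 and 3) of 17 gene lists (vertical axis) in 7 comparisons (horizontal axis), with the number of members higher and lower at an adjusted p under 0.05 of those measured printed in each cell. The stellate cell and matrix list had 22 of 23 members higher in ZZ against WT and 13 lower in ZZ LIRKO against ZZ.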

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

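The tests of the 3 patterns weighed here and the regrouping of residuals were chosen after the results were seen, while the counts over other splits of the samples were planned. The 2 bounds on the clock and pancreas patterns were also changed after a first result, as stated beside them.

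Some libraries stood far from the rest of their group. Chance picks about 1 in 20 groups, and 5 were found in 40 groups tested. The mean of the pancreatic genes was 0.97 log2 CPM in Z mouse 1410, against -4.28 to -3.58 in the other Z mice. Insr stood at 5.44 log2 CPM in Z LIRKO F1KO mouse 169, against 5.08 to 5.18 in the others. Xist stood at 5.95 log2 CPM in Z LIRKO mouse 1412, against 1.11 to 1.60 in the others, and at 0.31 in Z LIRKO F1KO mouse 206, against 1.25 to 1.51. The Y-linked Ddx3y stood at 6.08 and 6.13 log2 CPM in these 2 libraries and at 5.60 or more in all 43. Foxo1 stood at 5.91 log2 CPM in ZZ LIRKO mouse 1876, against 4.34 to 5.00.

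Differences between effects were tested themselves. The interaction of LIRKO and Z passed for 27 genes, but for 0 with the clock value as a covariate, without Z mouse 1442 or without LIRKO mouse 1468. It had Timeless at 1.72, Rassf4 at 1.55, Rgs3 at 1.50, Per1 at -3.04, Adam11 at -2.38 and Rarres1 at -1.82 log2 units. The F1KO difference, which also holds FOXO1 loss itself, passed for 901 genes, with Tcf24 at 5.62, Slc10a2 at 5.55, Elovl3 at 5.19, Slc22a28 at 4.60, Lepr at -4.50, Serpinb1a at -4.26, Tbc1d30 at -3.83 and Olig1 at -3.53. The interaction of LIRKO and ZZ passed for 1061 genes, with Cyp17a1 at 5.80, Mfsd2a at 3.26, G0s2 at 2.84, Nr4a1 at -4.61, Ppp1r3g at -4.33 and Abcc4 at -3.92.

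Clock genes differed between WT and Z, with clock values 2.10 log2 units apart on average. They ran from -0.73 to 1.48 in WT, 0.025 to 3.59 in Z and over 5.34 in ZZ LIRKO, the widest. Ranges cannot tell if time or feeding state at collection, not labelled, moved the means. ZZ differed from WT by -0.10 (SE 1.11), and with 3 mice a group this does not exclude an effect of the PiZ transgene, which cannot be told apart from time of collection. A bound of 1 SE and 50% of the difference, used first, would have excluded the transgene by a narrow margin. With the clock value as a covariate, 300 genes passed in Z against WT.

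Pancreatic genes stood high in some livers. The WT mice kept 1 order, 1586 above 1601 above 1564, for 9 of 9 pancreatic genes in both tables, so pancreatic tissue in some samples may be the source. Loss of the insulin receptor as the whole cause was argued against by 3 of 24 libraries of groups with LIRKO that lay above 0 log2 CPM, the highest at 6.47. The bound of 3 was set after the result and only just met. It replaced a first test on WT mouse 1564 alone, since 1 library near the floor excludes nothing. No other biological explanation was tested.

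WT mouse 1564 held more of some LIRKO genes in the hemizygous than in the homozygous table. Over 6 genes at least 4 log2 units higher in every LIRKO than in every WT library of the homozygous table (H19, Igfbp1, Lepr, Ppp1r3g, Rasal1, Slc4a9) its excess was a median 5.81% of the LIRKO level (quartiles 3.79 and 6.33%), so RNA or reads of a LIRKO library may be present in it. Counting that differed between the tables may be part, hardly all, of this excess, as the other WT mice had medians up to 0.772%. A Z LIRKO library as the source was argued against by the human transgene, at 21.6 CPM in this library where 144 were needed and other libraries without PiZ reached 25.4. If so, the hemizygous table understates the LIRKO changes of these genes, and the fits without the Prss2 libraries (569 genes in Z against WT, 1218 in LIRKO against WT), whose only WT library this is, are affected. No biological explanation was tested.

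Other splits of the samples were counted for each comparison. Chance was excluded for Z against WT (1 of 56 splits as large, real 1418, highest other 496), LIRKO against WT in the hemizygous table (1 of 35, real 3229, highest other 1738) and the homozygous table (1 of 35, real 3803, highest other 1261). It was also excluded for Z LIRKO against Z (1 of 100, real 4669, highest other 3219), Z LIRKO F1KO against Zstar (1 of 100, real 3196, highest other 1529), Zstar against Z (1 of 100, real 1288, highest other 305) and ZZ LIRKO against ZZ (1 of 100, real 3666, highest other 533). For the F1KO difference (1 of 100, real 901) the highest other, 900, was too near to exclude chance. For ZZ against WT the 10 splits were too few for a share under 0.05 (real 4149, highest other 0). For the interaction of LIRKO and Z 4 of 100 splits were as large (real 27), a share under 0.05, but the highest other gave 866, which points to a structure of the samples. For the interaction of LIRKO and ZZ chance was not excluded, with 14 of 100 splits as large (real 1061), and the highest other, 4300, again points to a structure of the samples: these splits exchange PiZ labels and so bring the PiZ effect into the contrast.

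With both main effects kept, only residuals were regrouped, in a fit of the 4 groups alone, again with the real grouping counted among the 100. For the F1KO difference 1 of 100 was as large (real 674, highest other 8). For the interaction of LIRKO and ZZ it was 1 of 100 as well (real 1061, highest other 1). This argued against chance for these 2 by this test. For the interaction of LIRKO and Z 2 of 100 were as large, and the highest other, 21, equalled the real 21.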

How the results depend on the processing

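For the 225 pairs of a named gene and a comparison, 5061 alternative fits were made. Of these 4774 kept the direction and the side of the threshold, 275 no longer passed, 11 newly passed and 1 reversed. C9 in Z LIRKO F1KO against Zstar stood at -1.32 and, with Z in place of Zstar, at 0.11. C9 was higher in Zstar than in Z, which by construction moves this value. edgeR and DESeq2, planned for recovered reads, were not run. No paired analysis was possible because the groups compared within a table share no animal numbers. Where no cause is given below, the cause was not tested. Read depth limits low genes, and a gene with 3 reads stood at -2.47 and -4.21 log2 CPM in the 2 tables.

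Requiring a change of at least 1 log2 unit, which by construction removes small changes, left 462 of 1418 genes in Z against WT, 1075 of 3229 and 1081 of 3803 in LIRKO against WT of the hemizygous and homozygous tables, 1170 of 4669 in Z LIRKO against Z. It left 969 of 3196 in Z LIRKO F1KO against Zstar, 400 of 901 in the F1KO difference, 401 of 1288 in Zstar against Z, 1563 of 4149 in ZZ against WT, 1007 of 3666 in ZZ LIRKO against ZZ and 542 of 1061 in the interaction of LIRKO and ZZ. With this minimum 673 were higher and 296 lower in Z LIRKO F1KO against Zstar, 1296 higher and 267 lower in ZZ against WT, and 119 higher and 423 lower in the interaction of LIRKO and ZZ.

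Without libraries above 0 log2 CPM of Prss2, which leaves fewer samples and only WT mouse 1564, assumed to vary like the other groups, the counts were 569 (392 higher, 177 lower) in Z against WT, 1218 and 1707 in LIRKO against WT of the 2 tables and 3092 in Z LIRKO against Z. They were 1692 in Z LIRKO F1KO against Zstar, 344 in the F1KO difference, 1964 in ZZ against WT (1232 higher, 732 lower) and 340 (98 higher, 242 lower) in the interaction of LIRKO and ZZ. With the clock value as a covariate the counts were 300 (206 higher, 94 lower) in Z against WT, 1511 in LIRKO against WT of the hemizygous table and 0 in the interaction of LIRKO and Z by limma (824 at an unadjusted p under 0.05, and 9 passed with voom weights without the covariate). In fits of the compared groups alone 942 passed in Z against WT and 715 in Zstar against Z. The interaction of LIRKO and Z gave 13 with quantile normalization, 174 with library weights and 9 with voom weights (5 higher and 4 lower, against 8 and 19). Library weights gave 1890 in the F1KO difference, and the direct comparison of Z LIRKO F1KO with Z LIRKO gave 3062. Zstar in place of Z gave 2181 against WT.

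Of 352 gene set tests 134 were called, and 0 by camera with an estimated correlation (31 at an unadjusted p under 0.05), 96 by fry and 131 after median scaling. The ratio of the median change in Z LIRKO F1KO against Zstar to that in Z LIRKO against Z was 39.9% for higher genes when these were taken from LIRKO against WT, against 21.1%, and 46.6% for lower genes, against 37.0%.

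With each mouse left out in turn, counts ranged from 879 to 1560 in Z against WT, 2168 to 3082 and 2700 to 3421 in LIRKO against WT of the 2 tables, 3614 to 4599 in Z LIRKO against Z and 2349 to 3238 in Z LIRKO F1KO against Zstar. They ranged from 535 to 1072 in the F1KO difference, 846 to 1347 in Zstar against Z, 3126 to 3801 in ZZ against WT, 2548 to 3750 in ZZ LIRKO against ZZ, 0 to 50 in the interaction of LIRKO and Z and 442 to 1159 in that of LIRKO and ZZ. Counts moved over 1.5 times without WT 1564 (880) or 1586 (879) in Z against WT, Z LIRKO 1428 (535) in the F1KO difference and Z 1445 (846) in Zstar against Z. They also did without ZZ 1682 (442), ZZ 1809 (578), LIRKO 1483 (588), WT 1586 (656), LIRKO 1474 (662) or LIRKO 1468 (690) in the interaction of LIRKO and ZZ. The interaction of LIRKO and Z gave 0 without Z 1442 or LIRKO 1468 (1154 and 1171 at an unadjusted p under 0.05), and 2 without WT 1586. It gave 6 to 9 without Z 1443 or 1445, LIRKO 1483 or 1474, Z LIRKO 1427, 1428 or 1450 or WT 1564 or 1601, and 50 without Z 1410.

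Of the named pairs 197 kept their call in every fit without 1 mouse and 28 did not. In the interaction of LIRKO and Z, Per1 lost it in 13 of 16 such fits (-3.25 to -2.62), Rarres1 in 13 (-1.89 to -1.42), Rgs3 in 15 (1.31 to 1.61), and Rassf4 in 7 (1.38 to 1.55). Adam11 (-2.44 to -2.20) and Timeless (1.57 to 1.74) lost it without Z 1442, LIRKO 1468 or WT 1586. In Z against WT, Gpx2 lost it without WT 1564 or 1586 (2.67 to 2.90), Socs2 without WT 1586 (-1.97) and Onecut1 without Z 1442 or 1445 or WT 1564 or 1586 (-2.68 to -2.14). Idi1 in LIRKO against WT lost it without WT 1601 (-1.48). In ZZ against WT, Elovl3 lost it without WT 1564, ZZ 1809 or ZZ 1682 (-3.29 to -2.74), Serpina1a without WT 1564 or ZZ 1682 (-0.87 to -0.58), Serpina1b without any WT mouse or ZZ 1682 (-0.68 to -0.32) and Serpina1d without WT 1564 (-1.20). In ZZ LIRKO against ZZ, Serpina1a lost it in 6 of 10 fits (0.29 to 0.71), Serpina1c without ZZ 1809 (-0.62) and Serpina1d without ZZ LIRKO 1810 or ZZ 1682 (0.40 to 0.99). Serpina1b in Z LIRKO F1KO against Zstar lost it in 5 of 10 (-0.45 to -0.41) and Mup16 in Zstar against Z in 8 of 10 (3.35 to 4.34), and Foxo1 there without Z 1443 (-0.39). In the F1KO difference, Lyz2 lost it in 9 of 19 (1.07 to 1.23), Vsig4 in 14 of 19 (0.47 to 0.57) and Olig1 without Z LIRKO 1428 (-3.33). In contrast Derl3 passed without Zstar 285 (2.14) and Igfbp1 without Zstar 120 or Z LIRKO F1KO 207 (-2.93 to -2.72). In the interaction of LIRKO and ZZ, Cd14 lost it without ZZ 1682 (-1.52), Mfsd2a without WT 1586, ZZ 1809 or ZZ 1682 (2.92 to 3.11) and Nr4a1 without LIRKO 1468, WT 1601, WT 1586, ZZ 1809 or ZZ 1682 (-4.75 to -4.11).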

Other observations

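Genes of mitochondrial respiration were lower in ZZ than in WT and higher in ZZ LIRKO than in ZZ. Both comparisons hold the ZZ mice, which favours opposite directions by chance alone. In ZZ against WT, of the nuclear genes of the respiratory chain 9 fell and 18 did not pass (9 fell over the list alone), with camera adjusted p = 0.00105, estimated 0.486. Of the mitochondrially encoded genes 5 fell and 7 did not pass (7 fell over the list alone), with camera adjusted p = 0.00947, estimated 0.277. The ATP synthase gene mt-Atp6 (-0.61 ± 0.12, adjusted p = 0.00136, limma) fell, but did not pass without the Prss2 libraries (-0.61). In ZZ LIRKO against ZZ, of the nuclear genes 20 rose and 7 did not pass (22 rose over the list alone), with camera adjusted p = 3.05e-13, estimated 0.137. Atp5b (0.81 ± 0.09, adjusted p = 1.08e-05) and the complex III gene Uqcrfs1 (0.75 ± 0.08, adjusted p = 1.25e-05) rose. Of the mitochondrially encoded genes 6 rose and 6 did not pass (8 rose over the list alone), with camera adjusted p = 1.63e-04, estimated 0.122. The gene mt-Nd3, of complex I, rose by 0.97 ± 0.14 log2 units (SE, adjusted p = 1.04e-04). In the interaction of LIRKO and ZZ 3 of 12 mitochondrially encoded genes had larger values, and 5 over the list alone (camera adjusted p = 0.00105, estimated 0.245). None of the 27 nuclear genes passed either way, although their list was called for larger values (camera adjusted p = 0.033, estimated 0.72) and, in the interaction of LIRKO and Z, for smaller ones (camera adjusted p = 0.00447, estimated 0.752, 0 genes passed). In LIRKO against WT of the hemizygous table, of the nuclear genes 10 rose and 17 did not pass (11 rose over the list alone), with camera adjusted p = 0.00307, estimated 0.748, and 17 rose and 10 did not pass (19 rose over the list alone) in the homozygous table, with camera adjusted p = 3.60e-08, estimated 0.722. In Z LIRKO F1KO against Zstar 5 fell and 22 did not pass (4 fell over the list alone), with camera adjusted p = 0.00154, estimated 0.553. In the F1KO difference 7 of 27 had smaller values, and 7 over the list alone (camera adjusted p = 2.10e-04, estimated 0.964).

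Coagulation and complement genes were lower in both comparisons of LIRKO in PiZ livers of the hemizygous table. In Z LIRKO against Z, 3 rose, 13 fell and 9 did not pass (3 rose and 15 fell over the list alone), with camera adjusted p = 0.0119, estimated 0.596. C8a (-2.46 ± 0.19, adjusted p = 2.04e-09) and C6 (-2.75 ± 0.32, adjusted p = 6.87e-07), of the complement attack complex, fell. Pros1, which encodes the anticoagulant protein S, rose by 0.92 ± 0.10 log2 units (SE, adjusted p = 3.19e-07). In Z LIRKO F1KO against Zstar, 11 fell and 14 did not pass (13 fell over the list alone), with camera adjusted p = 1.64e-05, estimated 0.406. C9 fell (-1.32 ± 0.27, adjusted p = 8.79e-04), but with Z, where C9 was lower, in place of Zstar its change was 0.11 and did not pass. Of the glycolysis genes 6 fell and 8 did not pass (7 fell over the list alone) in this comparison, with camera adjusted p = 0.00511, estimated 0.464. The fructokinase gene Khk (-0.60 ± 0.13, adjusted p = 0.00224) fell.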
